A study of Mus musculus with 2 samples.

How the data were processed

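The samples were 2 pools of epidermal total RNA, 1 from floxed littermate controls (CON) and 1 from mice with Vdr deleted in keratin 14 expressing cells (KO), each made of RNA from 3 mice at postnatal day 5, per the labels. The grouping was taken from the titles and genotypes in the labels. RNA was labelled with biotin, detected with streptavidin and Cy3 and read on a mouse bead array, per the labels' protocols. The arrays were processed with GenomeStudio 2011.1, per the submitters' processing notes.

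The authors deposited a non-normalized table with an average bead intensity on a linear scale for each of 25697 probes. The authors also deposited a detection p-value per probe, per the file headers. The authors' normalized intensity table held the same detection p-values, with 0 probes differing. Its sorted signals in both arrays agreed within 0.3 and none was near 0, the pattern of quantile normalization without background subtraction. The series matrix held the same values, with 0 probes differing, so its scale is linear and not centred. Bead standard errors and bead numbers were not analysed here.

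The non-normalized intensities were put through neqc in limma 3.58.1 (R 4.3.3). That function corrects the background with a normal-exponential model, using negative control values inferred from the detection p-values, adds an offset of 16, and applies quantile normalization and log2. The inferred background had a mean of 137.94 and an SD of 8.31 in CON, and of 141.93 and 9.27 in KO. The lowest raw signal was 114.9 in CON and 118.1 in KO, and the highest 35931.3 and 35763.7. The offset and the background model shrink or widen the log2 change of dim genes, so a fold at low signal depends on them. The later steps were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

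Gene names in the tables were those of the array design and many were old. They were updated through a RefSeq gene table of assembly GRCm38.p6, which named 25376 probes, 16938 by Entrez identifier, 7420 by accession, 553 by synonym and 465 by symbol. The file's name was kept for 321 probes. The assembly behind the array annotation is not given in the sources used here, so the table was used only for names and for which genes neighbour each other. The probes covered 17871 gene symbols. A gene was represented by its probe with the highest mean log2 signal. Of 2211 genes with at least 2 detected probes, 50 were 1.5-fold changed by the brightest probe. The second probe moved in the same direction for 38 of these and by 1.5-fold for 20. Across genes, which are not independent replicates, the log2 changes of both probes had a Pearson correlation of 0.35.

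A gene was called detected with a detection p-value under 0.01 in at least 1 pool. This gave 8865 genes, of which 8274 were detected in both pools, 312 in CON alone and 279 in KO alone. A change was called by size, at 1.5-fold or more, with 2-fold as a stricter count. With 1 pool per genotype no p-value, standard error or SD between groups was computed. Pooling also hides the spread between mice. Where a gene was undetected in a pool, its fold was given as a lower bound, set against the higher of its own signal and the lowest signal among detected probes of that array. Such a bound holds on the background-corrected scale only. List medians were also taken with such genes at their bounds, a step added after the data were seen, and are given where they moved by over 1.5 times.

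Gene lists for 36 groups, the comparisons, the thresholds and the rule for named genes were chosen before the data were examined. For a list with at least 4 detected members, the median log2 change was placed among the medians of 10000 random lists of the same size, drawn from detected genes in the same 10 classes of mean signal. A percentile below 2.5 or above 97.5 was called outside the limits. Of 31 lists with a percentile 5 lay above and 5 below, where 1.55 were expected outside by chance if lists were independent, which they are not, since some share genes. The percentiles describe these pools only and are not tests of the genotype.

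The genes named in the text were Vdr, then the 12 genes with the largest rise and the 12 with the largest fall among detected genes with at least 1.5-fold change and the same direction in the authors' normalized values. In each list with at least 4 detected members up to 4 with the largest absolute log2 change followed. In the lists closest to the series title any further member changed 1.5-fold was added, and in others members changed 2-fold. Any other gene was chosen after its values were seen and is marked so.

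The steps were tested on simulated data for 17871 genes with the background of the real arrays, a noise SD of 0.1 on the log2 scale per array and 200 changed genes. The rule recovered 36.8% of genes changed 1.5-fold, 88.4% of those changed 2-fold and 98.6% of those changed 3-fold. It also called 628 of 9657 unchanged genes at 1.5-fold and 55 at 2-fold. Of 60 simulated lists without a shift 0 lay outside the limits, and of 20 lists shifted by 0.2 all 20 lay above. That shift was added to the final log2 changes, and the simulated noise was independent between genes. The lists therefore tested the percentile step alone, and not for genes that vary together or share signal. The noise of the real arrays was not measured, since each pool was hybridised to a single array.

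Alternatives were the authors' normalized table, the series matrix, no background correction, centring on the 75th percentile in place of quantile normalization, an offset of 50, a detection p-value under 0.05, detection in both pools, no detection filter, the mean over a gene's detected probes and the 2-fold threshold. Added after the data were seen were a filter on a mean log2 signal of at least 8, the wound list without the Serpinb3 and stefin A families and the hair list without keratin-associated proteins.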

Results

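Gene expression was measured in the epidermis of mouse pups at postnatal day 5, in animals labelled as lacking the vitamin D receptor (Vdr) in keratinocytes and in their littermates. The knockout was made with Cre recombinase driven by the keratin 14 promoter, which is active in basal keratinocytes, acting on a floxed Vdr gene. The control group (CON) was made of floxed littermates without Cre. Back skin was split with dispase, and the epidermal RNA of 3 mice was pooled for each genotype. Each pool was measured on a bead array with 25697 probes. The series title names the joint action of the calcium sensing receptor and the vitamin D receptor in epidermal differentiation as the question. In the CON pool 11501 probes (44.8%) were detected above the negative controls, and in the KO pool 11422 probes (44.4%). The raw median signal was 153.6 in CON and 158.5 in KO. With 1 pool per genotype there was no spread between replicates, so no difference below has a test, and the number of arrays limits the precision.

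Vdr transcript was not lower in the pool labelled KO. The brightest of 3 Vdr probes read a raw signal of 1913 in CON and 2442 in KO, a log2 change of 0.33 after normalization. The second probe changed by 0.37 on the log2 scale and the dimmest by -0.23. The deleted part of the gene and the probe positions are not given in the sources used here, and a probe outside the deleted part checks nothing. The probes therefore did not check the labels, and each direction given here rests on the pool labelled KO being the knockout.

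Genes of vitamin D signalling and of calcium handling differed little between the pools. Of 12 detected genes for vitamin D metabolism and response, 0 changed by the 1.5-fold rule. Rxra, the receptor's dimer partner, had a log2 change of -0.48, Trpv6, an epithelial calcium channel, of 0.48. Cd14 was not detected in KO, with a lower bound of 1.09-fold on its fall. The list had a median log2 change of -0.06, at percentile 18.2 of random lists matched on size and signal. The enzymes that make and degrade the active vitamin, Cyp27b1 and Cyp24a1, were not detected in either pool, and neither was the calcium sensing receptor gene Casr. Of 18 detected calcium handling genes 0 changed, with a median of -0.02 at percentile 36.0. Atp2c1, the calcium pump of the Golgi, was lower by just under the 1.5-fold limit, at -0.58.

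Among 8865 genes detected in at least 1 pool, 275 passed the 1.5-fold rule as higher and 202 as lower in the pool labelled KO. Of these calls 178 were of genes not detected in 1 pool, and with such genes at their lower bounds 201 were higher and 125 lower. At 2-fold these counts were 40 and 12. The median log2 change over the detected genes was near 0 and the SD across them was 0.30. Dim genes supplied most of the calls, with 170 changed genes in the lowest of 10 signal classes and 8 in the highest. In simulated arrays 628 of 9657 unchanged genes (6.50%) passed the same rule, against 477 of 8865 (5.38%) in the data, so the total count did not exceed what simulated noise gave. Among genes with a mean log2 signal of at least 8, a filter added after the data were seen, 66 of 5106 were higher and 43 lower, while 1 of 4998 unchanged genes passed in the simulation. The simulated noise SD of 0.1 was a setting, and the noise of the real arrays was not measured. Simulated background was drawn separately for each array and added to signals that already held the real background's noise. This can overstate how far noise moved dim genes. Neither simulated rate therefore shows how many calls in the data were noise. In the authors' normalized values 48 genes were higher and 15 lower, so that 76.2% of the calls were higher, against 57.7% in the main values. Without background correction 50 were higher and 23 lower, or 68.5%.

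**Figure D1:**
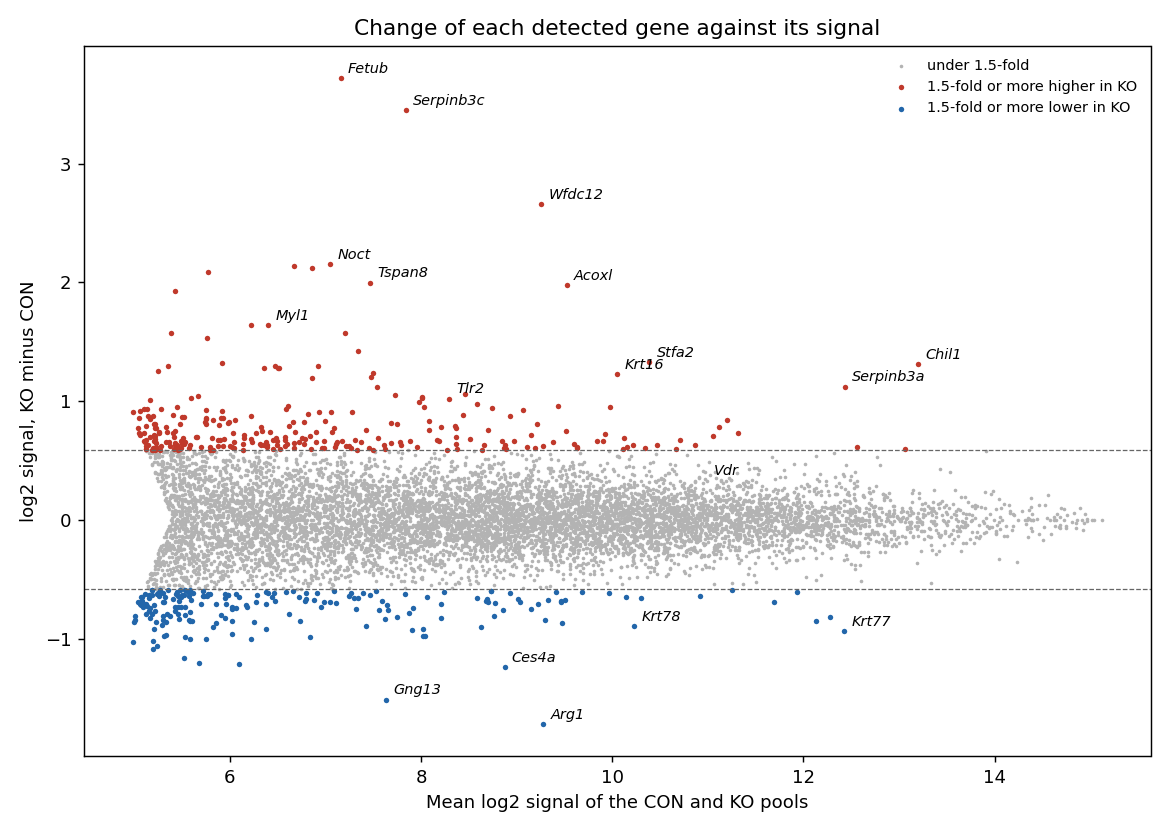
Log2 change (KO minus CON, y axis) of each of 8865 detected genes against its mean log2 signal over both pools (x axis), with dashed lines at 1.5-fold and coloured points beyond them. The spread was widest at low signal, where 170 of the 477 changed genes lay in the lowest of 10 signal classes, and Serpinb3c, Wfdc12, Acoxl and Arg1 stood clear of the other genes at their signal.

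The genes that rose most in the pool labelled KO were Fetub, which encodes the secreted protease inhibitor fetuin-B, Serpinb3c, a serpin of the squamous cell carcinoma antigen family, and Wfdc12, a small secreted inhibitor with a whey acidic protein domain. Serpinb3c rose 10.9-fold and Wfdc12 6.32-fold. Fetub was not detected in CON and rose at least 12.4-fold in the background-corrected values. Ahsg, the gene of fetuin-A that lies beside Fetub, was also not detected in CON and rose at least 2.01-fold on that scale, and Scgb1b27, a secretoglobin, at least 2.69-fold. The second Ahsg probe was detected in neither pool, with raw signals of 132.3 in CON and 162.9 in KO. Noct, a rhythmically expressed gene, rose 4.45-fold, Serpinb6d 4.41-fold, the phosphodiesterase gene Pde1b 4.34-fold, Tspan8 4.0-fold and Acoxl, a relative of the peroxisomal acyl-CoA oxidases, 3.94-fold. Myl1, a myosin light chain of skeletal muscle, and Serpinb3d rose 3.12-fold and 3.11-fold. These lower bounds and folds depend on the background model. In the authors' normalized values, which keep the background, Serpinb3c was 4.34-fold, Wfdc12 4.18-fold and Noct 2.15-fold higher, and the signal ratios of Fetub, Scgb1b27 and Ahsg were 3.91, 1.73 and 1.64.

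The falls were smaller and fewer. Arg1, which encodes arginase, fell by 1.72 on the log2 scale, from a raw signal of 1230.7 to 473.1, which is 3.29-fold. Gng13, a G protein subunit, fell 2.86-fold, the carboxylesterase gene Ces4a 2.36-fold and the pseudogene Pisd-ps2 2.31-fold. In the authors' values the falls were 2.56-fold for Arg1, 1.91-fold for Ces4a and 1.83-fold for Gng13, while Pisd-ps2 at 1.40-fold no longer passed the rule. The other 8 genes among the 12 largest falls were not detected in the KO pool, and their folds are lower bounds. Those were at least 1.83 for Tedc1, 1.80 for Adam3, 1.62 for Olfr538 and 1.60 for Ticam1. For Smco3, Serinc5, Bag2 and Zscan25 the lower bound was under 1.5, at 1.28, 1.26, 1.23 and 1.06. The ratios of these 8 in the authors' values were 1.27 to 1.34, under the rule. Of the 12 genes, 9 had a mean log2 signal under 7. Among bright genes outside the naming rule, chosen after their values were seen, the chitinase-like gene Chil1 rose by 1.31 on the log2 scale and Krt78, a keratin, fell by 0.89.

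**Figure D2:**
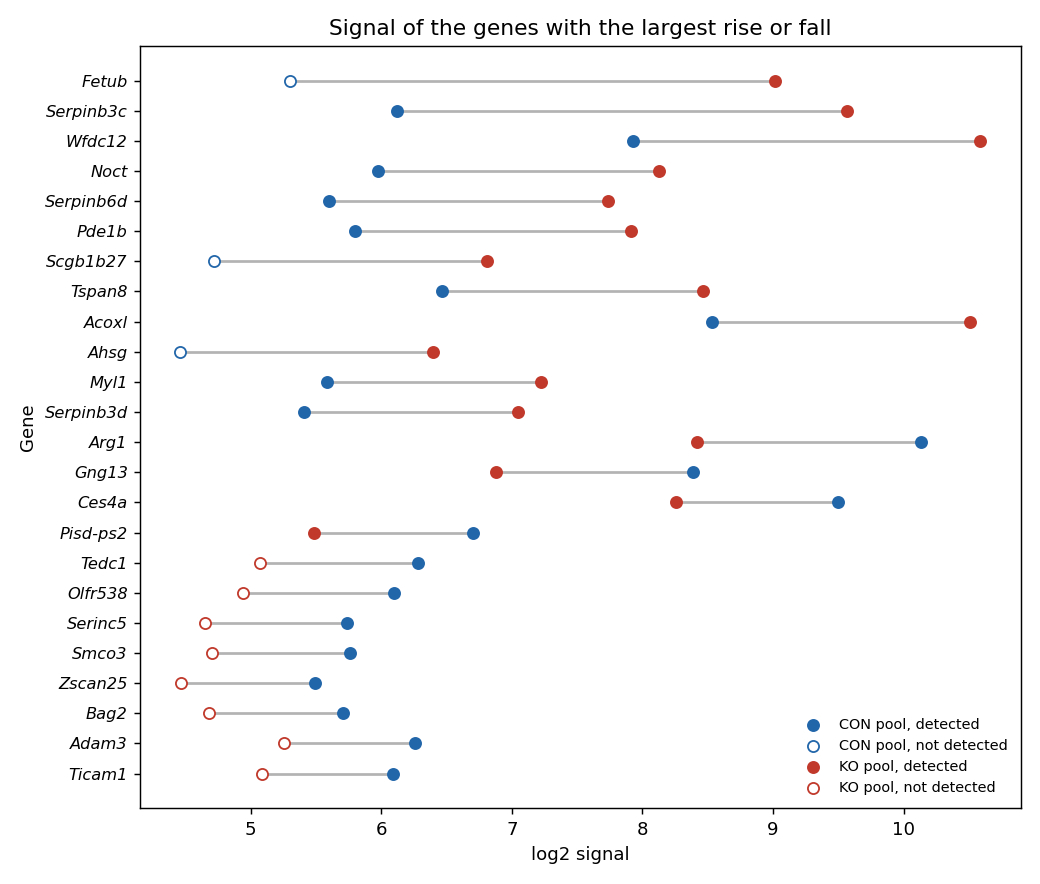
Log2 signal (x axis) of the 12 genes with the largest rise and the 12 with the largest fall (y axis) in the CON pool (blue) and the KO pool (red), with open circles for a gene not detected in that pool. In 3 of the risen genes the CON signal was not detected, and in 8 of the fallen genes the KO signal was not detected.

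Wound, stress and alarmin genes of keratinocytes were higher in the pool labelled KO. Of 24 detected members 7 rose and 0 fell, and the median log2 change of 0.20 lay at percentile 100 of random lists. All 7 also passed the rule in the authors' values. Besides Serpinb3c and Serpinb3d, the related Serpinb3a rose 2.17-fold from an already high raw signal of 3819.7. Krt16, a keratin induced in wounded epidermis, rose 2.34-fold, and the cysteine protease inhibitor gene Stfa2 2.51-fold. Serpinb3 and stefin A genes have near-identical relatives, and signal shared between their probes was not measured. Without both families, an alternative added after the data were seen, 2 of 17 members rose, 10 had positive and 7 negative log2 changes, and the median was 0.14. With undetected members included, the list's percentile was 95.4.

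Among 11 detected antimicrobial and pattern recognition genes 3 rose, namely Wfdc12, the lipopeptide receptor gene Tlr2 (2.03-fold) and the beta-defensin gene Defb14 (1.52-fold). Defb14 was 1.40-fold higher in the authors' values, under the rule. The list had 8 positive and 3 negative log2 changes, and its median of 0.12 lay at percentile 93.9, inside the limits. Over genes detected in both pools the median was 0.21, at percentile 99.6. Of 9 detected small proline-rich and group 3 late envelope genes, precursors of the cornified envelope, Sprr2d rose 1.73-fold and Sprr1b 1.66-fold (1.45-fold and 1.52-fold in the authors' values). Their list had a median of 0.19 at percentile 97.55, just above the upper limit, and inside the limits at percentile 97.0 after centring on the 75th percentile of signal.

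**Figure D3:**
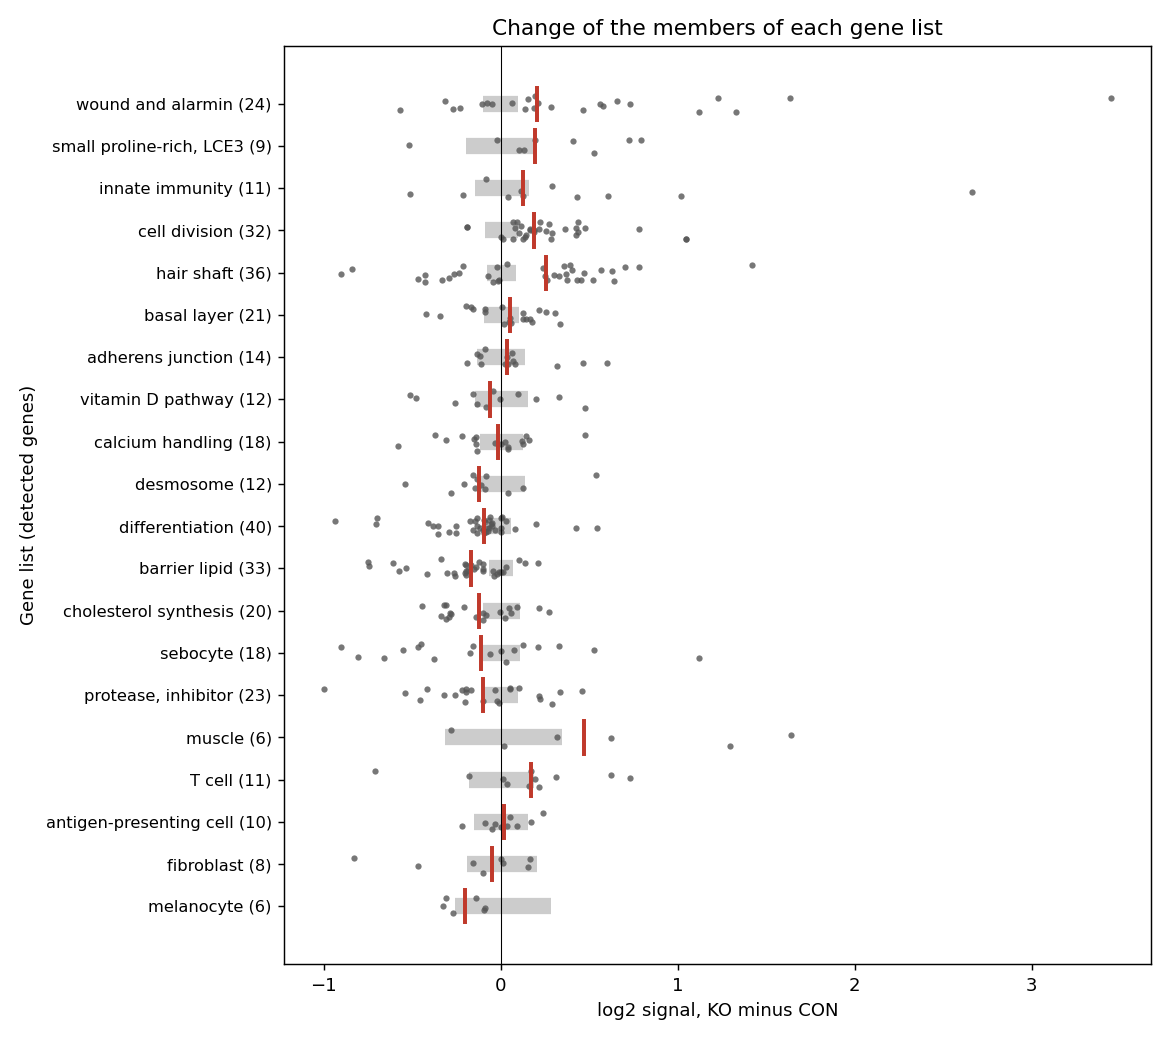
Log2 change (KO minus CON, x axis) of each detected member (points) of 20 gene lists (y axis, with the number of detected genes), with the list median as a red bar and the middle 95% of medians of matched random lists in grey. The red bars of the wound and alarmin, small proline-rich, cell division, hair shaft and muscle lists lie to the right of the grey ranges. Those of the differentiation, barrier lipid, cholesterol synthesis, sebocyte and protease lists lie to the left. The small proline-rich and sebocyte bars lie only just beyond their ranges.

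Markers of keratinocyte differentiation were slightly lower as a group. Of 40 detected suprabasal and cornified layer genes 31 had negative and 6 positive log2 changes, and the median of -0.09 lay at percentile 0.17. The members that fell were Krt77, a suprabasal keratin (1.91-fold), Krt80 (1.63-fold) and Grhl3, a transcription factor of epidermal barrier formation (1.62-fold). Krt77 kept a 1.90-fold fall in the authors' values, while Grhl3 at 1.44-fold and Krt80 at 1.37-fold did not pass the rule. None rose, and Rptn, which encodes repetin, had the highest change at 0.55. The 21 detected basal layer genes did not follow. Their median was 0.05 at percentile 83.2 and 0 of them changed.

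Cell junction genes showed little change. In the E-cadherin complex 1 of 14 detected genes rose, Vcl, which encodes vinculin (1.52-fold, and 1.41-fold in the authors' values), and Ctnnb1, the gene of beta-catenin, had a log2 change of 0.47. The median of this list was 0.04 at percentile 70.4. Of 12 detected desmosomal genes 0 changed, with a median of -0.12 at percentile 3.79 and opposite values for the desmosomal cadherins Dsc3 (-0.54) and Dsg3 (0.54). In the authors' values these were -0.44 and 0.21. Dsg3 was dim, with raw signals of 175.3 in CON and 206.4 in KO, so its value depends on the background correction. Of 12 detected tight junction genes 0 changed, with a median of 0.02 at percentile 62.5.

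Genes for the lipids of the skin barrier were lower in the pool labelled KO. Of 33 detected genes for ceramides and lamellar body lipids 27 had negative log2 changes, and the median of -0.17 lay at percentile 0, below all 10000 random lists. The lipase genes Lipk and Lipn fell 1.68-fold and 1.53-fold. Degs2, a sphingolipid desaturase and hydroxylase gene, fell 1.67-fold, and the ceramide synthase gene Cers4 had a log2 change of -0.57. Lipk fell 1.51-fold in the authors' values, and Lipn at 1.42-fold and Degs2 at 1.37-fold did not pass the rule. Cholesterol synthesis genes had a median of -0.12 at percentile 1.16 over 20 genes, of which 0 changed, with -0.32 for Cyp51 and -0.44 for Insig1. Over genes with a mean log2 signal of at least 8 the cholesterol list lay at percentile 4.21, inside the limits.

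Sebocyte genes went both ways. Of 18 detected members the wax synthase gene Awat2 fell 1.87-fold, the lipid droplet gene Plin2 1.58-fold and Scd3, which was not detected in KO, by 0.81 on the log2 scale, with no lower bound above 1. Mc5r, a melanocortin receptor gene of sebaceous glands, rose 2.17-fold. Awat2 and Mc5r also passed the rule in the authors' values, at 1.57-fold and 1.55-fold, and Plin2 at 1.39-fold did not. The list's median of -0.11 lay at percentile 2.22, and over genes detected in both pools at percentile 12.9. With Scd3 at its bound the median was -0.03.

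Hair shaft genes were higher as a list, mainly through keratin-associated proteins. Of 36 detected hair shaft and inner root sheath genes 5 rose and 2 fell, and the median of 0.26 lay at percentile 100. The keratin-associated protein genes Krtap9-3 and Krtap19-4 rose 2.67-fold and 1.72-fold (1.70-fold and 1.63-fold in the authors' values). Hair keratins did not move together. Krt35 fell 1.79-fold, and Padi3, an enzyme gene of the inner root sheath that was not detected in KO, fell at least 1.82-fold on the background-corrected scale (a ratio of 1.26 in the authors' values). The remaining risen members, chosen after their values were seen, were Krt86 (0.70 on the log2 scale), Krtap19-1 (0.64) and Krtap6-5 (0.63). In the authors' values 3 members rose and 1 fell, since Krtap19-1, Krtap6-5 and Padi3 no longer passed the rule. The 14 keratin-associated protein genes had a median of 0.42 and the 14 hair keratins -0.01. Without the former, an alternative added after the data were seen, the list's median was -0.03 at percentile 25.8.

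Follicle stem cell and signal genes, hedgehog genes and Wnt genes stayed within the range of random lists. The 17 detected follicle genes had a median of 0.04 at percentile 72.2 (mean -0.03) and 0 of them changed. Fgf22, a fibroblast growth factor gene, had the lowest value at -0.51. Of 6 detected hedgehog genes 0 changed, with a median of 0.07 at percentile 70.4, 0.44 for the cyclin gene Ccnd2 and -0.06 for the ligand gene Shh. Of 25 detected Wnt genes, the antagonist gene Nkd2 and the ligand gene Wnt10b fell 1.54-fold and 1.53-fold, but 1.30-fold and 1.21-fold in the authors' values. The Wnt median was -0.04 at percentile 23.6, and -0.12 at percentile 1.76 with each gene's detected probes averaged.

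Cell division genes were higher in the pool labelled KO. Of 32 detected members 30 had positive log2 changes, and the median of 0.19 lay at percentile 99.99. Nusap1, a spindle protein gene, rose 2.07-fold, the mitotic cyclin gene Ccnb1 1.72-fold, and the G1 cyclin gene Ccne1, not detected in CON, at least 1.74-fold. Nusap1 rose 1.53-fold in the authors' values, and Ccnb1 at 1.42-fold and Ccne1 at a ratio of 1.29 did not pass the rule. The thymidylate synthase gene Tyms had a log2 change of 0.48. DNA repair genes had a median of -0.05 at percentile 19.3 and a mean of 0.05 over 21 genes, of which Ercc5 rose 1.53-fold (1.42-fold in the authors' values).

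Desquamation proteases and their inhibitors were lower as a list, with a median of -0.10 at percentile 1.245 over 23 genes, of which Klk9 fell 2.0-fold and Klk6 and St14 had log2 changes of -0.54 and -0.46. In the authors' values Klk9 was 1.33-fold lower, under the rule, and the list lay at percentile 6.55, inside the limits. Of 13 interferon-induced genes 0 changed (median -0.10, percentile 14.7). Of 20 immediate early and heat shock genes 1 changed, Klf2, which was not detected in KO, with a lower bound of 1.25-fold (median -0.04, percentile 22.4). Among 14 clock genes 4 passed the 1.5-fold rule, in both directions. Bhlhe40 and Arntl rose 2.03-fold and 1.58-fold, and Cry2 fell 1.55-fold. Bhlhe40 rose 1.56-fold in the authors' values, while Arntl at 1.23-fold and Cry2 at 1.27-fold did not pass the rule. Npas2, the other of the 4, was not detected in KO and had a lower bound of 1.01-fold on its fall. The clock list had a median of -0.03 (-0.02 with undetected genes at their bounds), a mean of 0.03 and a percentile of 34.4. Ribosomal protein genes, which are abundant in all cells, had a median of 0.01 over 28 genes at percentile 73.9. Of the noncoding RNAs, H19 and Xist were detected, with log2 changes of 0.12 and 0.31. The second Xist probe was detected in both pools and changed by 0.03. Both Xist probes were dim, with raw signals of 188.9 and 190.2 in CON.

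Markers of skeletal muscle were higher at low signal. Of 6 detected skeletal muscle genes 3 passed the rule, namely Myl1, Myh8 (at least 1.53-fold) and Acta1, whose lower bound was 1.04-fold. The muscle median of 0.47 lay at percentile 99.7, and at 94.4 with undetected members included. With 3 members at their bounds the median was 0.19, and in the authors' values only Myl1 passed the rule, at 1.64-fold. Markers of T cells had a median of 0.17 at percentile 96.4 over 11 genes. Cd2 rose 1.66-fold (1.22-fold in the authors' values). Cd7 and Klrk1 were each detected in a single pool, with a lower bound of 1.24-fold on the rise of Cd7 and of 1.002-fold on the fall of Klrk1. In the authors' values the T cell list lay at percentile 99.0, outside the limits. Antigen-presenting cell markers had a median of 0.02 at percentile 57.7 over 10 genes, with 0.24 for the Langerhans cell gene Cd207.

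Fibroblast markers had a median of -0.05 at percentile 29.6 over 8 genes, of which the collagen gene Col1a1 fell 1.78-fold (1.24-fold in the authors' values). Melanocyte markers had negative log2 changes in all 6 detected genes, with -0.33 for the pigment gene Pmel and a median of -0.20 at percentile 6.07. Nerve and Merkel cell markers had a median of 0.38 at percentile 94.9 over 4 genes, 0 of which changed. Of these 3 were not detected in CON, and with them at their bounds the median was 0.23. Lists with fewer than 4 detected members gave single values, named after they were seen. The adipocyte genes Lpl and Cfd changed by 0.67 and -0.44 on the log2 scale, the vessel genes Acta2 and Egfl7 by 0.70 and 0.08, and the erythroid genes Hba-a1 and Slc4a1 by -0.69 and 0.50. Car2 was not detected in CON. Of the mast cell genes 0 were detected. Of the sex-linked genes, the Y-linked Ddx3y had a log2 change of -0.05 and Xist of 0.31 (0.03 by its second probe). The list of 4 genes lay at percentile 93.5. With 2 of the 4 at their bounds its median was 0.20, against 0.30. The list joins Xist with Y-linked genes, which a difference in sex makeup would move in opposite directions. Its median and percentile therefore do not show the sex makeup of the pools.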

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

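The filter on a mean log2 signal of at least 8, the hair shaft and wound lists without their gene families and the bounds for undetected genes were chosen after the results were seen; the other alternatives were planned. Vdr kept its direction and stayed under 1.5-fold wherever it was recomputed, with 0.29 in the authors' values and 0.16 as the mean over its probes. The number of changed genes depended on the fold threshold and on how dim signals were treated. Against 275 higher and 202 lower genes, the authors' normalized values and the series matrix each gave 48 and 15 (76.2% higher), and 47 and 15 of these were also among the 275 and 202. No background correction gave 50 and 23 (68.5%), an offset of 50 gave 102 and 57, the 2-fold threshold 40 and 12 (76.9%), and the signal filter 66 and 43. Detection in both pools left 114 lower genes, and setting genes undetected in 1 pool at their bounds left 201 higher and 125 lower. The last 4 settings call fewer genes by construction. Of the 141 named genes, 106 stayed on the same side of 1.5-fold and 35 fell under it in the authors' values, and 0 reversed. The 12 largest rises and 12 largest falls were named for having the same direction there, so they could not reverse.

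Among lists, protease genes left the limits with a median of -0.054 in the authors' values and the series matrix, -0.053 without background correction, -0.075 with 75th percentile centring, -0.081 with an offset of 50, -0.066 with a detection p under 0.05 and -0.021 without a detection filter. T cell markers passed them with 0.140 in the authors' values and the series matrix, 0.154 without background correction, 0.168 with an offset of 50 and 0.163 without a detection filter. Innate immunity genes passed them with 0.109 without background correction, 0.206 when detected in both pools, 0.118 without a detection filter and 0.360 under the signal filter. The small proline-rich list left them with 0.192 after centring, 0.195 with a detection p under 0.05, 0.117 without a detection filter and 0.195 under the signal filter. Sebocyte genes left them with -0.090 after centring, -0.060 when detected in both pools and -0.055 without a detection filter. Without a detection filter the wound list (0.065) and muscle markers (0.101) left the limits, while nerve markers (0.191) and sex-linked genes (0.295) passed them. Averaging probes moved the Wnt list outside (-0.119), and the signal filter moved the cholesterol list inside (-0.090). The hair shaft list reversed to -0.031 without the keratin-associated proteins, which made up its rise. For the other lists the cause was not tested.

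No paired analysis was possible because each genotype was a single pool, and for the same reason no replicate could be left out. The signal over background limited dim genes most, where the SD of the log2 change was 0.45 in the lowest of 10 signal classes and 0.17 in the highest.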

Other observations

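All tests below were chosen after the results were seen, except those of all neighbouring pairs and of the respiratory chain genes, whose outcomes were set out before they were computed. Some of the former use values of planned lists or of the planned setting without background correction, but their use to weigh a cause was not planned. Gene groups defined after the data were seen also differed between the pools. Of 34 detected histone genes 31 had positive log2 changes in the pool labelled KO, 6 rose and 0 fell, and the median of 0.41 lay at percentile 100. H3c7 rose 2.42-fold, H3c6 1.83-fold and H2ac22 1.75-fold, alongside the higher cell division genes. In the authors' values the histone median was 0.19 and 3 of the 6 passed the 1.5-fold rule, with H3c6 at 1.58-fold and H2ac22 at 1.56-fold, while H3c7 at 1.49-fold did not. Histone genes are closely related in sequence and their probes could share signal, which percentile 100 does not address. Of 67 detected respiratory chain genes 47 had positive and 19 negative log2 changes, 4 rose and 0 fell, and the median of 0.09, a 1.06-fold difference, lay at percentile 100. None of the 4 passed the rule in the authors' values, where they were 1.16-fold to 1.43-fold higher.

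Neighbouring genes changed together mainly where they were related. On the gene order of the reference, 24 neighbouring pairs changed in the same direction, 18 higher and 6 lower, and 28 of 10000 shuffles of the changes had as many (median 13). Of these pairs 14 were of related genes, where shuffles had a median of 0, and 10 of unrelated genes, where shuffles had a median of 12 and 7805 of 10000 had as many. Genes were called related when their symbols shared the first 3 letters or they belonged to the cystatin or Ly6 families. This rule was chosen after the results were seen. Ahsg with Fetub, Fetub with Kng1, Cstdc6 with Stfa2 and Lypd2 with Slurp2 were related by family only. The split into related and unrelated pairs therefore depends partly on the families named. Serpinb3a, Serpinb3d, Serpinb3b and Serpinb3c rose side by side, as did Ahsg, Fetub and Kng1, and Lipk and Lipn fell together. The second Ahsg probe was not detected in either pool. Signal shared between probes of related genes was not measured.

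The wound and alarmin genes were higher in the pool labelled KO. Without background correction the median was 0.199, against 0.203 with it, at percentile 100 in both, which argues against that correction of dim probes as the cause. A larger share of antigen-presenting cells is not a likely source, because their markers lay at percentile 57.68 with 0 of 10 risen. A larger share of T cells was not tested as a source. T cell markers lay at percentile 96.4 and at 99.0 in the authors' values. Their median and highest log2 changes were 0.17 and 0.73, against 0.20 and 3.45 in the wound list. Signal shared within the Serpinb3 and stefin A families stays open, because the list without them lay at percentile 97.84 but at 93.27 to 98.75 when 1 further gene was left out. The genotype and other differences between the pooled mice stay open too and were not tested.

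The barrier lipid genes were lower in the pool labelled KO. Without background correction the median was -0.150, against -0.165 with it, at percentile 0 in both, which argues against that step as the cause. A smaller share of suprabasal keratinocytes stays open. The lipid median was lower than the differentiation median by a difference of -0.073, with a 95% bootstrap interval over genes of -0.13 to 0.013. An interval that holds 0 does not separate the lists, but it does not show that they fell alike. The bootstrap also treats genes as independent. A smaller share of sebocytes also stays open, because sebocyte genes lay at percentile 2.22. They lay inside the limits after 75th percentile centring (3.35), over genes detected in both pools (12.9) and without a detection filter (13.5). Under the other planned settings with list values they stayed outside, with 0.55 in the authors' values. The lipid list without sebocyte genes lay at percentile 0, but this removed 1 of 33 genes and tested little, and the genotype was not tested apart from either share.

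The hair shaft list was higher in the pool labelled KO through keratin-associated proteins. The keratin-associated protein median exceeded the hair keratin median by 0.43 (95% bootstrap interval over genes 0.12 to 0.69). A larger share of hair follicle cells that raised both groups alike would give no such difference. One that raised them unequally stays open. The comparison was chosen after the results were seen, and the bootstrap treats genes that may share signal as independent. Signal shared between the near-identical keratin-associated proteins cannot be told apart from a true change of these genes. The list without them lay at percentile 25.84, which would follow in either case. The genotype and a difference in hair follicle stage between the pooled mice stay open and were not tested.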
